A study of Mus musculus with 8 samples.

How the data were processed

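Gene expression was measured by 3′ mRNA sequencing in 8 libraries of mouse bone-marrow-derived macrophages, 4 wild type (WT) and 4 Grn knockout (GrnKO), all given the vehicle DMSO. Per the labels' protocols, marrow of several mice was pooled for each biological replicate, differentiated with M-CSF, frozen, thawed and cultured before RNA extraction, and libraries carried unique molecular identifiers so that PCR duplicates could be removed. The estimated counts per gene were made by the authors with Salmon against GRCm39, per the submitters' processing notes; the Salmon version is not given in the sources used here. Of the non-zero estimated counts deposited, 36.4% were not whole (tolerance 1e-06), and no filter was stated. A companion table deposited by the authors holds log2 CPM (counts scaled to library size) with a prior count added, so that every 0 shares a common lowest value. The deposited log2 values served only as an alternative. A gene table gave the symbols, and the sample sheet was not used.

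Groups came from the sample titles. Estimated counts were rounded to whole numbers, and library totals ran from 5828180 to 8768770. Of 56980 genes, 12186 passed edgeR's filterByExpr and were tested. The main comparison used edgeR 4.0.16 in R 4.3.3, with TMM normalization, robust dispersions and the quasi-likelihood F test of GrnKO against WT. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called; an edgeR adjusted p below is from this test. Fold changes are GrnKO over WT, and their standard errors (SE) follow from the F statistic. CPM values use TMM-scaled library sizes. For a pair of libraries of the same group, the chi-square statistic per degree of freedom over genes was at least 2.91, so no library was a repeat of another. The median log2 fold change of all tested genes was -0.03 with TMM, -0.03 with median-of-ratios factors and -0.10 with no factors.

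There were 31 gene lists, of which 26 had 5 or more tested members and were tested with camera of limma 3.58.1 (preset correlation 0.01), adjusted over these lists. Each list call was repeated with the correlation between genes estimated from the data and with fry. A list gives a count of called members over all genes tested and a count adjusted over the list alone. Sex-linked genes were given as values only. The share of called genes near Grn was compared with that of all other tested genes by a two-sided Fisher's exact test. Gene order for that test came from GENCODE M21 on GRCm38, matched on gene ID; that build differs from the authors', so no coordinates are printed.

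Genes were named by a rule. It took Grn; the 10 largest log2 fold changes in each direction among called genes with separated groups, a mean CPM of 5 or more in the higher group and a symbol that is not a predicted model; the next 5 per direction by p; up to 4 called members of each list, or up to 2 as values where none was called; and Gpnmb, Lgals3, Ctsd, Tmem106b, Psap, Sort1 and Trem2. Of the genes it selects, 1 is not reported here. The rule, the lists, the tests and most alternatives were fixed before the data were examined. Alternatives were other scaling factors, 2 other filters on low counts, DESeq2 1.42.0, limma-voom, limma-trend on the deposited CPM with pseudocounts of 1 and 0.25, non-robust dispersions, the replicate number as a block, leaving out each library, an adjusted p under 0.01 and a minimum fold of 1.2. A cell cycle covariate, thinned counts and the deposited log2 values as given were added later.

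The procedure was tested on counts simulated for 12186 genes with these libraries' sizes and dispersions, of which 12041 passed the filter. For this comparison it recovered 66 of 66 genes changed 4-fold, 51 of 67 changed 2-fold and 21 of 67 changed 1.5-fold, and 10 of 153 calls were false. Genes with smaller changes are therefore often missed with these libraries. Recovery was not measured separately for genes of low expression, so these rates cannot be extended to them, even for 4-fold changes.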

Results

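Progranulin, encoded by Grn, is a secreted glycoprotein that reaches the lysosome and is processed there. The series asked how constitutive loss of Grn alters the transcriptome of macrophages grown from mouse bone marrow. Libraries of 3′ mRNA tags were made from 4 WT and 4 GrnKO cultures, each a biological replicate pooled from several mice. WT libraries held 7413220 to 8768770 counts and GrnKO libraries 5828180 to 7944860; the totals did not differ beyond chance (two-sided exact permutation test over 70 assignments, p = 0.0857). RNA integrity numbers were 9.9 or 10 in every library. Other library measures did not overlap between genotypes. TMM factors were 0.994 to 1.046 in WT and 0.964 to 0.991 in GrnKO libraries. The 10 most counted genes held 6.64 to 9.43% of counts in WT and 9.57 to 10.8% in GrnKO libraries. The first principal component (32.3% of variance), with the GrnKO libraries at positive and the WT libraries at negative scores, separated the genotypes. The second (26.8%) spread the WT libraries from 32.7 in replicate 1 to -41.3 in replicate 4, against -1.98 to 23.5 in the GrnKO libraries.

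Grn (ENSMUSG00000034708.13) was nearly absent from the knockout libraries. It stood at 1436, 1498, 1700 and 2027 CPM in WT replicates 1 to 4 and at 14.4, 12.96, 13.6 and 12.99 CPM in GrnKO replicates 1 to 4. The mean fell from 1665 ± 266 to 13.5 ± 0.69 CPM (SD, n = 4 per group), leaving 0.81% of the WT level. The log2 fold change was -6.95 ± 0.15 (SE; edgeR quasi-likelihood test, adjusted p = 4.1e-10), and all 8 libraries matched their labels. The assay counts tags at the 3′ end of transcripts, and the labels do not say which part of the gene was deleted, so the 73 to 102 remaining counts per library do not tell what kind of transcript was left.

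GrnKO macrophages had higher transcripts of the sterol synthesis genes Hmgcs1 and Msmo1 and the fatty acid handling genes Scd1 and Fabp4. The lysosomal proteases Ctsd and Ctss also rose. Transcripts fell for the receptors Cx3cr1 and Ccr2, which guide monocytes, for the complement gene C1qa and for S100a8 and S100a9, listed as neutrophil markers. Among the genes that rose were Gpnmb and Lgals3, which mark lipid-laden and disease-associated macrophages. The fatty acid binding protein Fabp5 rose from 298 ± 56.4 to 1504 ± 60.7 CPM and the transmembrane glycoprotein Gpnmb from 1516 ± 256 to 4267 ± 526 CPM. The fractalkine receptor Cx3cr1 fell from 257 ± 133 to 27.9 ± 6.43 CPM (SD, n = 4 per group). In all, 518 of 12186 tested genes were called, 340 higher and 178 lower in GrnKO, and 225 of these changed at least 2-fold (150 higher, 75 lower). The groups did not overlap in 513 of the called genes; 1459 of all tested genes were separated in this way, against 2.86% of genes by chance.

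The number of genes called in GrnKO versus WT depended on which libraries were included, as did those of genes higher in GrnKO and genes lower in GrnKO. It was 942 without WT replicate 1 (530 higher, 412 lower), 287 without WT replicate 3 (201 and 86), and 319 without GrnKO replicate 1 (221 and 98). It was 267 without GrnKO replicate 2 (194 and 73), 272 without GrnKO replicate 3 (193 and 79) and 314 without GrnKO replicate 4 (232 and 82). Without WT replicate 4 it was 686, of which 283 were lower. DESeq2 called 831 genes, and edgeR called 918 when every gene with a count in any library was tested. With the cell cycle mean as a covariate, an alternative added later, edgeR called 1140.

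**Figure D1:**
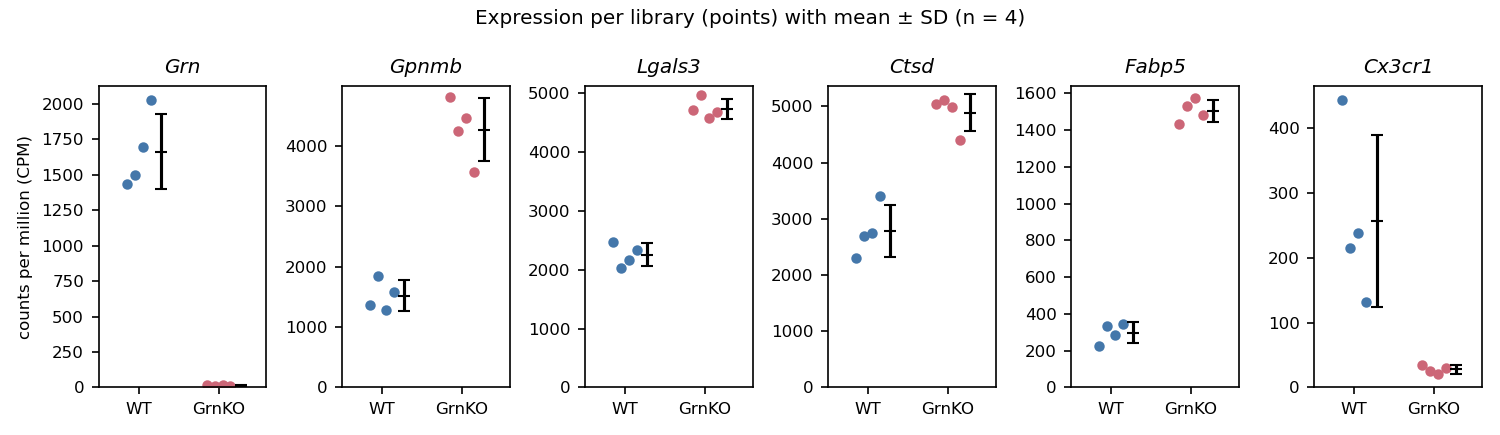
CPM (linear axes from 0) of Grn, Gpnmb, Lgals3, Ctsd, Fabp5 and Cx3cr1 in each library, with WT in blue and GrnKO in red; bars give the mean and SD of 4 libraries. The genotypes do not overlap for any of these genes, and Grn falls from a mean of 1665 to 13.5 CPM.

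Among separated genes with a mean of 5 CPM or more in the higher group, excluding predicted gene models, the largest increases included the lipid genes Mgll, Scd1 and Fabp4. Mgll, which encodes monoacylglycerol lipase, rose 14.6-fold, from 3.34 ± 1.08 to 48.9 ± 9.16 CPM (log2 fold change 3.87 ± 0.24, edgeR adjusted p = 6.2e-06). The stearoyl-CoA desaturase Scd1 rose by 3.40 ± 0.33 on the log2 scale, the metalloprotease Adamts1 by 3.24 ± 0.25, the deiodinase Dio2 by 3.00 ± 0.16, the tetraspanin Tspan7 by 2.85 ± 0.35 and the fatty acid binding protein Fabp4 by 2.80 ± 0.16. Stra6l (2.77 ± 0.34) and Bex1 (2.65 ± 0.42) completed this group, together with 2 genes that share the symbol Pakap (3.25 ± 0.31 and 3.02 ± 0.21), whose counts are uncertain because their reads could be split between overlapping entries. By smallest p, the cell cycle inhibitor Cdkn1c (2.61 ± 0.16), Fabp5 (2.34 ± 0.14; uncertain because of near-identical pseudogenes), the stress gene Gadd45a (2.19 ± 0.14), the RNA-binding protein Cpeb1 (2.17 ± 0.16) and macrophage elastase Mmp12 (1.49 ± 0.10) followed, with edgeR adjusted p of at most 3.1e-05.

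Under the same limits, which leave out genes of lower expression such as Olfml3 (named after its value was seen), the largest decreases after Grn were in Cx3cr1 (log2 fold change -3.21 ± 0.33), the kinase Dmpk (-2.96 ± 0.67), the calprotectin subunit S100a9 (-2.73 ± 0.37), the granule protein Ngp (-2.39 ± 0.55), the coagulation factor F13a1 (-2.31 ± 0.48), the transporter Slco2b1 (-2.19 ± 0.37), the calprotectin subunit S100a8 (-2.04 ± 0.33), the chemokine receptor Ccr2 (-2.03 ± 0.19) and the interferon-inducible GTPase Iigp1 (-2.02 ± 0.40). By smallest p, Id3 (-1.98 ± 0.16), the extracellular matrix protein Tgfbi (-1.34 ± 0.13), the oxysterol receptor Gpr183 (-1.22 ± 0.12), the dipeptidyl peptidase Ctsc (-1.22 ± 0.13) and the unannotated transcript AI504432 (-1.42 ± 0.15) followed, with edgeR adjusted p of at most 2.8e-04. Some of these genes varied widely among the WT libraries. From WT replicate 1 to WT replicate 4, S100a9 fell from 48.6 to 14.0 CPM and Dmpk from 12.6 to 1.63 CPM. F13a1 rose from 7.55 to 40.6 CPM, whereas Ccr2 varied less (44.4 to 56.6 CPM in WT). The calls of 4 of the decreased genes rested on the full set of libraries. Dmpk was not called without WT replicate 2 or any GrnKO library (edgeR adjusted p up to 0.11), F13a1 without WT replicate 3 or any GrnKO library (up to 0.071), Ngp without WT replicates 2 or 3 or GrnKO replicates 1, 3 or 4 (up to 0.12) and Iigp1 without GrnKO replicates 1, 2 or 3 (up to 0.065).

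Several genes of cholesterol synthesis and uptake rose. Of 26 tested members, 15 rose, none fell and 11 were not called, with a median log2 fold change of 1.10; adjusted over the list alone, 19 were called. Hmgcs1, the HMG-CoA synthase, rose from 107 ± 17.3 to 272 ± 35.7 CPM (log2 fold change 1.35 ± 0.14, edgeR adjusted p = 2.9e-04). The sterol methyl oxidase Msmo1 rose by 1.34 ± 0.12, mevalonate diphosphate decarboxylase Mvd by 1.57 ± 0.19 and the lathosterol desaturase Sc5d by 1.32 ± 0.16. The list was called by camera (adjusted p = 8.5e-31). Its members varied together across libraries, and the adjusted p was 0.073 by camera with an estimated correlation and 0.0050 by fry. WT replicate 4 was the lowest of the WT libraries on this list, at -0.41 relative to the WT mean on the log2 scale, against 0.12 to 0.15 in the other WT libraries and 0.70 to 1.17 in the GrnKO libraries.

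Of 36 tested liver X receptor (LXR) targets and lipid storage genes, 13 rose, none fell and 23 were not called (median log2 fold change 0.44); 20 were called adjusted over the list alone. Fabp4, Fabp5, Scd1 and the acyl-CoA synthetase Acsl3 (1.08 ± 0.13) had the smallest p; Scd2, named after its value was seen, rose more than Acsl3. This list was called by camera (adjusted p = 9.5e-21) and also with an estimated correlation (adjusted p = 7.9e-04). The scavenger receptor Cd36, another member, rose by 0.53 ± 0.10 (edgeR adjusted p = 0.015), a call not made without WT replicate 3, GrnKO replicate 2 or GrnKO replicate 3 (up to 0.062).

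**Figure D2:**
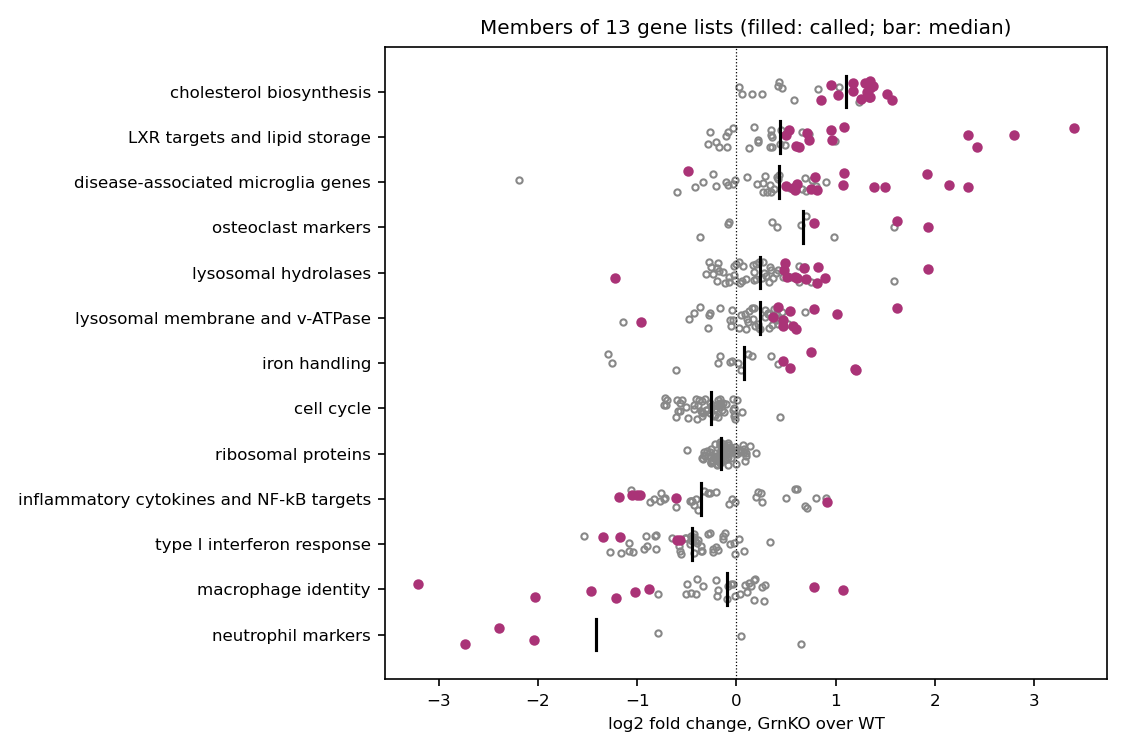
Log2 fold change of GrnKO over WT for each tested member of 13 gene lists; filled points are called genes, open points are not, and the vertical bar is the list's median. The cholesterol list has its median at 1.10 and no called member below 0, and the interferon list has its median at -0.45.

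Some lysosomal transcripts rose. Among 56 lysosomal hydrolases, 11 rose, 1 (Ctsc) fell and 44 were not called, with a median log2 fold change of 0.24; 21 were called adjusted over the list alone (20 higher, 1 lower). Cathepsin D (Ctsd) rose from 2785 ± 460 to 4885 ± 330 CPM (0.81 ± 0.12, edgeR adjusted p = 0.0029), cathepsin S (Ctss) from 2657 ± 131 to 4318 ± 392 CPM (0.70 ± 0.09, adjusted p = 0.0015) and cathepsin K (Ctsk) from 2.32 ± 1.04 to 8.96 ± 1.22 CPM. Among 53 lysosomal membrane and proton pump (v-ATPase) genes, 10 rose, 1 fell and 42 were not called (median 0.24), and 24 were called adjusted over the list alone (23 higher, 1 lower). Those that rose included the v-ATPase subunits Atp6v0d2 (1.62 ± 0.12) and Atp6v1c1 (0.60 ± 0.09), the chloride transporter Clcn7 (0.78 ± 0.11) and the GTPase Rragd (1.01 ± 0.19), which acts in lysosomal nutrient signalling. The member that fell was the acetyltransferase Hgsnat (-0.96), named after its value was seen. Both lists were called by camera (adjusted p = 9.0e-07 and 1.5e-07), with an adjusted p of 0.20 and 0.28 with an estimated correlation. The means of the membrane and v-ATPase list overlapped between genotypes. GrnKO replicate 4 (0.11 relative to the WT mean) lay below WT replicates 2 (0.14) and 4 (0.13), and WT replicate 1 was lowest (-0.24).

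Of 36 genes that earlier work linked to progranulin, 9 rose, 2 fell and 25 were not called (median log2 fold change 0.34), and 23 were called adjusted over the list alone (19 higher, 4 lower). Gpnmb rose by 1.49 ± 0.14 (edgeR adjusted p = 1.2e-04) and galectin 3 (Lgals3) from 2252 ± 193 to 4733 ± 168 CPM (1.07 ± 0.09, adjusted p = 7.5e-05), whereas the complement genes C1qa and C1qb fell. The lysosomal membrane protein Tmem106b (0.15 ± 0.14, edgeR adjusted p = 0.61), prosaposin, Psap (0.69 ± 0.20, 0.085), the progranulin receptor Sort1 (-0.35 ± 0.22, 0.44) and the microglial receptor Trem2 (0.27 ± 0.11, 0.22) were not called. Camera called the list (adjusted p = 3.2e-06), and the adjusted p was 0.11 with an estimated correlation. Of 44 disease-associated microglia genes, a signature of microglia near pathology, 14 rose, 1 fell and 29 were not called (median 0.43), and 31 were called adjusted over the list alone (28 higher, 3 lower). Fabp5, Lgals3, Gpnmb and Mamdc2 (2.14 ± 0.22) had the smallest p in it, and its call held with an estimated correlation (adjusted p = 5.1e-18 with the preset and 0.0097 with the estimated correlation). In these lists, 33 of the 36 and 30 of the 44 members also belonged to another list.

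Osteoclast markers were called higher as a list (adjusted p = 1.5e-07 by camera and 0.0098 with an estimated correlation). Of 12 tested, 3 rose (Atp6v0d2, Clcn7 and Ctsk), none fell and 9 were not called, with a median log2 fold change of 0.67. Adjusted over the list alone, 8 were called (7 higher, 1 lower). Of the 12, 6 also belonged to another list, and the 3 that rose were also members of the lysosomal lists above. Of 18 iron handling genes, 5 rose, none fell and 13 were not called (median 0.08), and 7 were called adjusted over the list alone (6 higher, 1 lower). They included the ferritin chains Fth1 (0.75 ± 0.13) and Ftl1 (0.54 ± 0.11), whose counts are uncertain because of near-identical processed copies, the ferrireductase Steap3 (from 23.5 ± 8.55 to 54.1 ± 4.01 CPM) and the transferrin receptor Tfrc (from 145 ± 65.1 to 335 ± 44.9 CPM). Camera called the iron list (adjusted p = 0.017) but not without WT replicate 1, which was its lowest WT library, the list means overlapped between genotypes, and the adjusted p was 0.12 with an estimated correlation. Tfrc was not called without WT replicates 2 or 3 or GrnKO replicates 1, 2 or 3 (edgeR adjusted p up to 0.086), nor Ftl1 without WT replicate 3 or GrnKO replicates 2, 3 or 4 (up to 0.069).

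Of 33 NRF2 oxidative stress genes, 4 rose (Cd36, Fth1, Ftl1 and the glutathione peroxidase Gpx4, 0.92 ± 0.20, uncertain because of a pseudogene), none fell and 29 were not called, and 5 were called adjusted over the list alone. Its median was -0.05 and its mean 0.08, and camera did not call it (adjusted p = 0.14). Of 33 glycolysis and hypoxia genes, 2 rose, aldolase C (Aldoc, 1.47 ± 0.16) and hexokinase 3 (Hk3, 1.13 ± 0.15), none fell and 31 were not called; 4 were called adjusted over the list alone. That list had a median of 0.18 and was called by camera (adjusted p = 7.5e-05), with an adjusted p of 0.20 with an estimated correlation. Gpx4 was not called without WT replicates 2 or 3 or GrnKO replicates 2, 3 or 4 (edgeR adjusted p up to 0.074).

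Some surface receptors that mark macrophages and monocytes changed, in both directions. Of 34 macrophage identity genes, 6 fell, 2 rose and 26 were not called (median log2 fold change -0.09), and 12 were called adjusted over the list alone (2 higher, 10 lower). Cx3cr1 fell to 27.9 CPM and Ccr2 from 50.2 ± 6.20 to 12.2 ± 3.65 CPM (edgeR adjusted p = 1.4e-04), while Lgals3 rose. Of 25 genes of alternative activation and scavenger receptors, 4 fell, 1 (Cd36) rose and 20 were not called (median -0.33), with 10 called adjusted over the list alone (4 higher, 6 lower). Tgfbi, F13a1 and the scavenger receptor Stab1 (-1.11 ± 0.23) were among those that fell. Camera called both lists (adjusted p = 0.0033 and 0.013), with an adjusted p of 0.32 and 0.20 with an estimated correlation. The second list was not called among genes with a mean of 5 CPM or more, and Stab1 was not called without WT replicates 2 or 3 or any GrnKO library (edgeR adjusted p up to 0.070). The list means overlapped between genotypes. WT replicate 1, the lowest WT library on both, stood at -0.24 relative to the WT mean on the first, below GrnKO replicates 1 (-0.21) and 2 (-0.22). It stood at -0.32 on the second, below GrnKO replicates 1 to 3 (-0.25 to -0.24).

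Of 15 complement genes, C1qa (from 400 ± 114 to 151 ± 3.99 CPM, log2 fold change -1.41 ± 0.17, edgeR adjusted p = 6.7e-04) and C1qb (-0.54 ± 0.13) fell, the complement regulator Cd59a rose (0.72 ± 0.15) and 12 were not called; 7 were called adjusted over the list alone (3 higher, 4 lower). The list had a median of -0.40 and was not called by camera (adjusted p = 0.064). C1qb was called with all libraries and without WT replicate 1, and without any other library its edgeR adjusted p was up to 0.11; Cd59a was not called without WT replicate 3 or GrnKO replicates 1 or 2 (up to 0.075).

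Of 6 tested neutrophil markers, S100a8, S100a9 and Ngp fell, the other 3 were not called and 4 were called adjusted over the list alone (median log2 fold change -1.41). S100a8 stood at 48.5 ± 26.1 CPM in WT and 11.9 ± 2.31 CPM in GrnKO libraries (SD, n = 4 per group). Camera called the list (adjusted p = 8.6e-05), with an adjusted p of 0.11 with an estimated correlation. Of the 23 listed neutrophil markers 17 had too few counts to be tested.

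Of 50 type I interferon response genes, 4 fell, none rose and 46 were not called, and 9 were called adjusted over the list alone. The median log2 fold change was -0.45. Ifi27l2a fell by 1.34 ± 0.20 on the log2 scale (edgeR adjusted p = 0.0027), a value that is uncertain because a close paralog could share its reads. The ADP-ribosyltransferase Parp14 (-0.57 ± 0.12), Slfn8 (-0.60 ± 0.13) and the oligoadenylate synthetase Oas2 (-1.18 ± 0.30) also fell. Camera called the list (adjusted p = 9.5e-08), with an adjusted p of 0.32 with an estimated correlation. The list means overlapped between genotypes: relative to the WT mean they were 0.58, 0.10, -0.30 and -0.38 in WT replicates 1 to 4 and -0.27, -0.69, -0.70 and -0.16 in GrnKO replicates 1 to 4. Parp14, Slfn8 and Oas2 each lost their call without at least 4 of the 8 libraries, with edgeR adjusted p up to 0.10, 0.10 and 0.16; these included GrnKO replicates 2, 3 and 4 for all 3 genes, GrnKO replicate 1 for Parp14 and Slfn8, WT replicate 3 for Parp14 and Oas2, and WT replicates 1 and 2 for Oas2.

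Of 38 inflammatory cytokine and NF-kB target genes, 5 fell, 1 rose and 32 were not called (median log2 fold change -0.35), and 16 were called adjusted over the list alone (5 higher, 11 lower). The inflammasome sensor Nlrp3 (from 45.2 ± 7.80 to 22.6 ± 2.03 CPM), the chemokine Ccl12 (-1.18 ± 0.22) and Marcksl1 (-1.05 ± 0.24) fell, and Tnfaip2 rose (0.91 ± 0.14). Camera called the list (adjusted p = 0.027) but not without WT replicate 1 or with the cell cycle mean as a covariate, and the adjusted p was 0.20 with an estimated correlation. The list means overlapped between genotypes. Marcksl1 was not called without WT replicate 2 or any GrnKO library (edgeR adjusted p up to 0.10).

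None of 56 cell cycle genes and none of 76 ribosomal protein genes was called by edgeR over all genes tested or adjusted over the list alone. Their median log2 fold changes were -0.26 and -0.15, and Cenpf (-0.70 ± 0.21, edgeR adjusted p = 0.090), Hmgb2 (-0.71 ± 0.21, 0.095), Rpl35a (-0.33 ± 0.09, 0.059) and Rps9 (-0.33 ± 0.10, 0.11) had the smallest p; the counts of Rpl35a and Rps9 are uncertain because ribosomal protein genes have many pseudogenes. Camera called both lists (adjusted p = 0.0041 and 2.4e-04), with an adjusted p of 0.66 and 0.36 with an estimated correlation, and not the cell cycle list without WT replicate 1 or with its own mean as a covariate. Cell cycle means ranged from -0.83 in WT replicate 4 to 0.64 in WT replicate 1 relative to the WT mean, a span that held all 4 GrnKO libraries (-0.39 to 0.20). The ribosomal protein means also overlapped between genotypes.

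**Figure D3:**
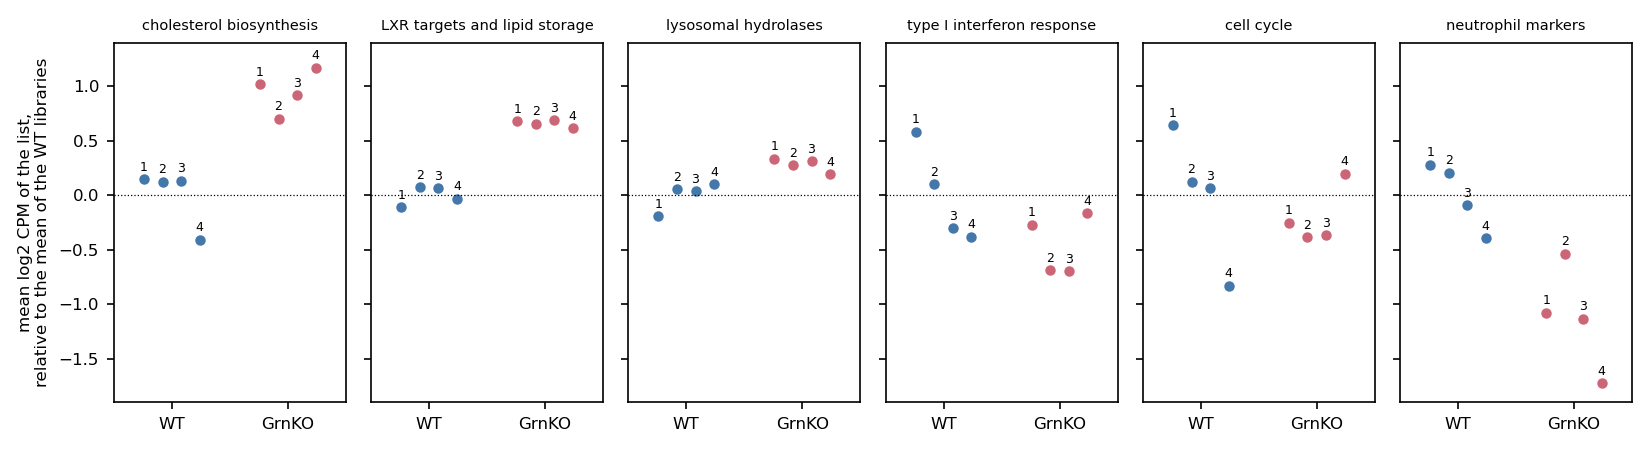
Mean log2 CPM of 6 gene lists in each library, relative to the mean of the WT libraries; numbers beside the points are replicate numbers. The genotypes are separated for the cholesterol, LXR and lipid storage, lysosomal hydrolase and neutrophil lists and overlap for the interferon and cell cycle lists.

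The remaining lists moved little. Autophagy had 1 called member of 38 (Tax1bp1, 0.57 ± 0.11; adjusted p = 0.054 without GrnKO replicate 3) and sphingolipid metabolism 1 of 35 (the galactosidase Gla, 0.82 ± 0.15), and camera called neither (adjusted p = 0.34 and 0.088). Antigen presentation had 1 of 31 (Ctss; camera 0.37) and the mitochondrially encoded genes 1 of 15 (mt-Nd3, 0.77 ± 0.14; camera 0.79). None of 66 nuclear oxidative phosphorylation genes was called over all genes tested or over the list alone; Cox5a (0.33 ± 0.11) and Cox6a1 (0.35 ± 0.12) had the smallest p, and camera did not call the list (adjusted p = 0.088). Of 43 ATF4 and unfolded protein response genes, Atf3 (0.87 ± 0.12) and the seryl-tRNA synthetase Sars (0.77 ± 0.18) rose, and camera called the list (median 0.13, adjusted p = 0.013) but not without WT replicate 4 or with an estimated correlation (adjusted p = 0.43). Its means overlapped between genotypes. Of 26 immediate early genes, Egr1 (1.92 ± 0.22), Gadd45b (1.38 ± 0.20) and Atf3 rose and Klf2 fell (-0.60 ± 0.13); the list's median was -0.03 and its mean 0.07, and camera did not call it (adjusted p = 0.28). Counts adjusted over the list alone were 1 for autophagy, 1 for sphingolipid metabolism, 3 for antigen presentation (1 higher, 2 lower), 1 for mitochondrially encoded, 2 for ATF4 and 5 for immediate early genes (4 higher, 1 lower). Sars was not called without WT replicates 2 or 3 or GrnKO replicates 2, 3 or 4, nor Klf2 without WT replicate 3 or GrnKO replicates 2, 3 or 4 (edgeR adjusted p up to 0.11 for both).

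Most markers of other marrow cell types had too few counts to test. Among those tested, the receptors Kit (from 1.13 ± 0.64 to 6.89 ± 0.39 CPM), a marker of mast cells and progenitors, and Il7r (from 173 ± 39.3 to 467 ± 55.8 CPM) rose, as did Vwf (0.98 ± 0.20), and the platelet chemokine Pf4 fell (-0.82 ± 0.12). Kit was the only called member of 9 dendritic cell and of 3 mast cell markers, Il7r of 3 lymphocyte markers and Vwf of 3 stromal markers, while all 3 erythroid and megakaryocyte markers (Tfrc, Vwf and Pf4) were called; adjusted over the list alone the counts were the same except for 2 stromal markers. The dendritic cell list was not called by camera (adjusted p = 0.070). Vwf was not called without GrnKO replicates 1, 2 or 3 (edgeR adjusted p up to 0.074). Of 5 sex-linked genes none was called over all genes tested or over the list alone, but 4 lay above 0 and 1 below (median log2 fold change 0.48). Xist stood at 88.2 ± 25.4 CPM in WT (55.8 to 116) and 50.3 ± 23.4 CPM in GrnKO (30.4 to 80.2). The Y-linked Ddx3y stood at 59.2 ± 29.5 CPM in WT (27.0 to 95.9) and 82.8 ± 14.3 CPM in GrnKO (67.1 to 99.6). Whether the sex mix of the pools differed between genotypes, or added to other changes, was not tested.

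A knockout allele made in another strain's cells can carry neighbouring sequence of that strain. Of 206 tested genes within 10 Mb of Grn, 8 (3.88%) were called, 4 higher and 4 lower, against 506 of 11849 other genes (4.27%). The odds ratio was 0.91 (95% confidence interval 0.38 to 1.83; two-sided Fisher's exact test, p = 1). They were Stac2, Fam117a, Dusp3 and Nfe2l1, which rose, and Igfbp4, Map3k14, Arhgap27 and Fmnl1, which fell; these names were taken after their values were seen.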

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

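The tests that left out WT replicate 1 or WT replicate 4 from a pattern below were chosen, with their limits, only after the per-library list means had been seen. The requirement that a limit still hold with 1 further library left out was put into the script after a first run had shown the medians. By their point values alone, the sterol genes without WT replicate 4 and the interferon genes with the cell cycle covariate would have passed their limits of 0.8 and -0.3, and those explanations would have been set aside. The same requirement was applied to the genes near Grn last, after their limits with a library left out had been seen. No value came from data outside the main measurement. In 250 groups of 4 libraries, 10 had a library far from the rest, no more than the roughly 5% of groups that chance alone gives.

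Ccr2 stood at 17.7 CPM in GrnKO replicate 1, against 10.2 to 10.6 in the other GrnKO libraries. Cpeb1 stood at 11.3 CPM in WT replicate 1, against 9.28 to 9.53 in the other WT libraries. Ctsd was lowest in GrnKO replicate 4 at 4396 CPM, against 4996 to 5112. C1qa was highest in WT replicate 2 at 569 CPM, against 325 to 363. Among list means on the log2 scale relative to the WT mean, WT replicate 4 stood at -0.41 for cholesterol biosynthesis (others 0.12 to 0.15). WT replicate 1 stood at -0.32 for alternative activation and scavenger receptors (others 0.07 to 0.14) and at -0.25 for iron handling (others 0.07 to 0.10). GrnKO replicate 4 stood at -0.48 for alternative activation and scavenger receptors (others -0.25 to -0.24), at -0.044 for ribosomal proteins (others -0.16 to -0.15) and at -0.050 for dendritic cell markers (others 0.41 to 0.44).

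Across the 35 splits of the 8 libraries into 4 and 4, only the real split (1 of 35) called as many as 518 genes. The highest count among the other splits was 0. The same held for the 340 higher (1 of 35) and the 178 lower genes (1 of 35). These results met the limits written beforehand. However, 1 of 35 is the smallest share this test can give, so it does not exclude chance. Every other split mixed the genotypes within a group, so a difference by genotype adds to its spread and lowers its calls. Chance cannot be excluded for the number of lists called by camera with its preset correlation. The real split called 17 lists, the highest of the other splits also called 17, and 2 of 35 splits reached that number. The 34 other splits called at least 3 lists each, with a median of 9. With its preset correlation, camera thus called lists in every split that mixed the genotypes. The other split that reached 17 lists set WT replicate 1 with GrnKO replicates 1, 3 and 4 against the rest. It kept part of the genotype contrast, so a difference by genotype could itself give list calls in it. The number of lists therefore cannot tell chance from genotype.

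Sterol synthesis genes had a median log2 fold change of 1.10 over 26 genes, of which 15 rose and 11 were not called. The list's adjusted p was 0.073 by limma's camera with an estimated correlation and 0.0050 by fry. The tables argue against a difference in proliferation between the libraries as the whole cause: with the cell cycle mean as a covariate the median was 1.21, and 1.15 to 1.29 when 1 further library was left out. The low WT replicate 4 stays open as a part of the size: without it the median was 0.91, but it ranged from 0.78 to 1.03 with 1 more library left out, which crosses its limit of 0.8. The genotype and a difference in culture or thawing that followed it were not separable, since no label gives a culture batch, and both stay open as untested.

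Interferon response genes had a median log2 fold change of -0.45 over 50 genes, of which 4 fell and 46 were not called; the list means overlapped between genotypes, and the list's adjusted p by limma's camera was 0.32 with an estimated correlation. Without WT replicate 1, the highest library, the median was -0.15, and -0.28 to -0.06 with 1 more library left out, so that library may account for much of the difference. With the cell cycle covariate the median was -0.31, and -0.39 to -0.04 with a library left out. Neither the high WT replicate 1 nor proliferation can be told apart from an effect of genotype: the medians with a library left out lay on both sides of -0.15, which each explanation needs the median to exceed, and those with the covariate also crossed -0.3. The genotype stays open as untested.

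Sequence of another strain carried beside the knockout allele would raise the share of called genes near Grn. The odds ratio was 0.91 and its 95% upper limit was 1.83, below the limit of 2 written before this test was run. With a library left out the upper limit ran from 1.33 to 2.52 and passed 2 without WT replicate 2 (2.17), WT replicate 3 (2.15) or GrnKO replicate 1 (2.52), and it was 2.28 with a window of 5 Mb. No excess of calls near Grn was seen, but these limits do not exclude such sequence, which stays open.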

How the results depend on the processing

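The cell cycle covariate, the thinned counts and the deposited log2 values as given were chosen after seeing the data. Limma-trend gave the same result on the deposited values as given and with a pseudocount of 0.25. Both had 525 calls, 466 of them main calls, so these refits are not separate checks. Grn kept its direction and call in all settings, with log2 fold changes from -7.01 to -6.84 with a library left out. The number of genes called in GrnKO versus WT, 518, stayed within 1.5 times with other scaling factors, a mean CPM filter of 5, limma-voom, limma-trend, non-robust dispersions and thinned counts (457 to 533). It was 831 with DESeq2 (517 genes higher in GrnKO, 314 genes lower in GrnKO), 918 with no filter beyond 1 count in any library (427 lower), 1140 with the cell cycle covariate (671 and 469), 209 at an adjusted p under 0.01 (157 and 52) and 276 against a minimum fold of 1.2 (194 and 82). The stricter threshold and the minimum fold lower the count by construction; the cause of the other shifts was not tested. DESeq2 shared 516 and the covariate fit 518 of the main calls. With a library left out the counts ranged from 267 to 942 (193 to 530 higher, 73 to 412 lower); WT replicate 1 gave the highest count, GrnKO replicate 2 the lowest total and lower count, and GrnKO replicate 3 the lowest higher count.

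Camera called 17 lists, 15 to 20 with a library left out, and 3 with an estimated correlation, which were the LXR and lipid storage, disease-associated microglia and osteoclast lists. Apart from the estimated correlation and fry, 12 of the 17 list calls held in every other setting run for lists. Fry did not call the interferon, macrophage identity, cell cycle and ATF4 lists. It did call the sphingolipid, complement, NRF2 and dendritic cell lists (fry adjusted p 0.046 to 0.047), which camera did not call. Of 77 named genes called apart from Grn, 57 kept their call in every refit with another method, filter or set of libraries in which they were tested (19 or 20 refits per gene), and 0 turned direction. At an adjusted p under 0.01, 54 were called, and 63 against the minimum fold; 54 passed all of these.

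For genes near Grn, none of the settings run (2 other windows, DESeq2, the replicate block and each library left out) gave a call; the odds ratio was 1.01 with a window of 5 Mb and ranged from 0.65 to 1.12 with a library left out, passing 1 without WT replicate 2 (1.03) and GrnKO replicate 1 (1.12). The cause was not tested.

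With the replicate number as a block (replicate block), 220 genes were called (168 higher, 52 lower), of which 217 were main calls. The numbers did not pair the samples: same-numbered libraries had residual correlations of -0.07, -0.14, 0.15 and -0.39, and 1 of 8 libraries correlated best with its own number.

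Small changes were often missed at these library sizes and this replicate number: in simulated counts 21 of 67 genes changed 1.5-fold were recovered. Recovery at low expression was not measured separately.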

Other observations

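The lists in this part were written after the main results had been seen; genes whose values were known by then, or that belong to the lists fixed before the data were examined, were left out of the tests, whose limits were written before the remaining genes were looked at. The reading of a median that goes against its prediction was changed after a first run, which affected the MITF and TFE list. Of 19 tested monocyte genes not seen before, 4 were called and all 4 fell: Clec4a1 (log2 fold change -1.11 ± 0.19, edgeR adjusted p = 0.0063), Spn (-1.08 ± 0.24, 0.029), the integrin Itgal (-1.07 ± 0.24, 0.029) and Ms4a6c (-0.66 ± 0.16, 0.037). In the whole list of 27 tested genes 7 fell and none rose, with Ccr2, Cx3cr1 and F13a1 among them. S100a4 (-0.04 ± 0.16) and S100a6 (-0.07 ± 0.12), also monocyte genes, were not called.

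A hypothesis is that GrnKO cultures held less of a monocyte programme than WT cultures. The 19 unseen members had a median log2 fold change of -0.29, with 14 below 0 and 5 above (camera with an estimated correlation, p = 0.034; adjusted over the 4 lists tried here, p = 0.14), so the test met its limit before but not after that adjustment. S100a8, S100a9 and Ngp, listed as neutrophil markers, also fell, but only 6 of the 23 listed markers could be tested. Kit, a marker of mast cells and progenitors, rose to a mean of 6.89 CPM, but only 3 of 14 listed mast cell markers could be tested and no other was called. The osteoclast list rose too (median log2 fold change 0.67, adjusted p = 0.0098 by camera with an estimated correlation), but its 3 called members also belonged to the lysosomal lists. A different mix of cell types or of mature cells may account for the lower monocyte genes. These few markers cannot show it, and it stays open as untested.

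Other hypotheses found no clear result. Several homeostatic microglia genes fell, among them Olfml3 (-2.63 ± 0.41) and Fcrls (-1.56 ± 0.29), but the 20 unseen members of that list had a median of -0.16 (16 below 0, none called; limma's camera with an estimated correlation, adjusted p = 0.87). Of 25 tested MITF and TFE targets outside the lysosome lists, 5 rose and 1 fell, but only 1 of those that rose was unseen. Leaving out genes already seen to rise tilts the remaining members against a shared rise. The 17 unseen members had a median of -0.11 (limma's camera, adjusted p = 0.87). That median went against the prediction and by its written limit set the hypothesis aside. After the first run, a p under 0.05 by fry was required as well. The fry p was 0.32, with 7 members above 0 and 10 below, so the hypothesis was read as undecided. For a shared lowering of TGF-beta targets, the 22 unseen members had a median of -0.058, with 11 on each side of 0 (limma's camera, adjusted p = 0.87). In that whole list of 27 tested genes, 5 fell and 2 rose.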
